A study of Desulfitobacterium hafniense Y51 with 4 samples.

How the data were processed

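RNA from 3 batch cultures and 1 river sediment sample was labelled with Cy3 and hybridised to Agilent 8 x 60K custom arrays designed on 2 Desulfitobacterium hafniense genomes, per the labels' protocols. The authors deposited the spot intensity values of each array as written by Agilent Feature Extraction 10.7.3.1, the version in the submitters' processing notes. Per the file headers, each array was scanned in both channels and the processed intensity was dye-normalized (linear and LOWESS) against the red channel, although the labels give 1 dye. The authors also deposited a matrix of normalized log2 values for 4824 locus tags and 4428 intergenic regions. Its normalization method is not given in the sources used here.

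The green channel alone was used. The dye normalization multiplied the median background-subtracted signal by 7.18 in river sediment and by 0.193, 0.459 and 0.576 in batch replicates 1, 2 and 3, so the processed signal served only as an alternative. Spot means were corrected against their local background medians with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and log2-transformed. Control spots and outlier-flagged spots were then left out, and the 2 spots of each probe averaged. Flagged outliers made up 1.67%, 7.78% and 9.14% of spots in batch replicates 1, 2 and 3 and 0.0478% in river sediment. Since under 50% of probes were well above background in river sediment, each array was scaled to its 75th percentile over the 3595 probes well above background on all 4 arrays. Probes well above background on every array of at least 1 group were kept (11548 of 21947), and probes sharing a target name were averaged. No probe was saturated.

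Differences were river sediment minus batch culture. They were tested with limma (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05, with river sediment assumed to vary like the batch cultures and 2 residual degrees of freedom. For the scanner values, limma took a single spread, 0.55 log2, for every probe target. Where a target was not well above background in a group, the fold was a lower bound. It was taken against the lowest signal among probes well above background on each array. Such a bound holds only for the scaling over the 3595 probes well above background on all 4 arrays. Locus tags and intergenic regions of the matrix were tested apart with the same model. The scanner files do not mark intergenic probes, and the matrix rows could not be tied to probes.

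The tests were tried on simulated arrays with 200 changed members, first using the spread of each member. For the 6324 probe targets, 0%, 2%, 58% and 96% of changes of 1, 2, 4 and 8 log2 were recovered, with 0 calls among unchanged targets. For the 4824 locus tags, 14%, 58%, 96% and 100% were recovered, with 3 such calls. That simulation does not match the real fit of the tags: limma's prior degrees of freedom were 1.74 in it and 5.87 in the data. The first simulation does not match the real fit of the probe targets, which took 1 spread for all. With that single spread, 2%, 38%, 98% and 100% of the changes were recovered over the 6324 probe targets, with 7 calls among unchanged ones. Each simulation changed 200 members, far fewer than passed in the data, so these counts do not estimate the false calls there.

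The test designs, a first set of alternatives and a rule for named genes were fixed before the data were examined. The removal of a probe GC trend, the restriction to probes usable on all arrays, the U and SH counts by scaling, the alternative fits of the locus tags, the locus tags without a block and the intergenic test without a repeated start were added afterwards. The rule took the pce genes, the 12 largest rises and 12 largest falls among called genes with a known product, and leading members of fixed gene lists. Neither the pce genes nor the lists could be applied, because the files used here give no symbols or products, and no list test was run. In place of that rule, chosen after the files were seen, the members named are the 2 largest rises and the 2 largest falls in each set, for probe targets outside the range of the batch cultures and well above background where higher, for locus tags among those past the threshold, and for intergenic regions among those past the threshold with a start of their own. Alternatives covered the signal column, scaling, filter, probe averaging, slide, variance model, threshold and each batch replicate left out. The contiguous stretch of tags that differed most from the rest was sought after its outline was seen in a plot, over stretches of more than 20 tags, and again from batch culture level alone. Plots were drawn with matplotlib.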

Results

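Transcript levels of Desulfitobacterium hafniense Y51, an anaerobic bacterium that can respire tetrachloroethene, were measured on 4 custom Agilent arrays. The batch culture group held 3 arrays of RNA from cultures grown with 30 mM fumarate and 20 mM lactate in 1010 ml, with 10 ml of pure hexadecane. The river sediment group held 1 array, of RNA from 30 g of sediment in 30 ml of anoxic artificial freshwater. The series title places the work in a microcosm study of bioaugmentation of sediment polluted with tetrachloroethene. Nothing in the labels says that the batch replicates came from separate cultures, so the spread between them may be technical. All p-values rest on that spread alone. For probe targets they rest on 1 value pooled over all targets, 0.55 log2, and not on each target's own spread. River sediment had no replicate, and its values carry no SD.

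River sediment gave less signal than batch culture. Of 21947 probes, 20.4% were well above background in river sediment (exact binomial 95% interval 19.9 to 21). The shares were 60% (59.3 to 60.6), 51.9% (51.2 to 52.6) and 50.9% (50.2 to 51.6) in batch replicates 1, 2 and 3. The gap depended on the limit of detection: above the 95th percentile of the negative control spots stood 58.8% of probes in river sediment, against 74.9%, 63.1% and 62.6% in batch replicates 1, 2 and 3. The 99th percentile of raw green signal was 6.58 times the median of the negative control spots in river sediment. It was 887, 519 and 648 times that median in the 3 batch cultures. The number of arrays limits the precision of every comparison.

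**Figure D1:**
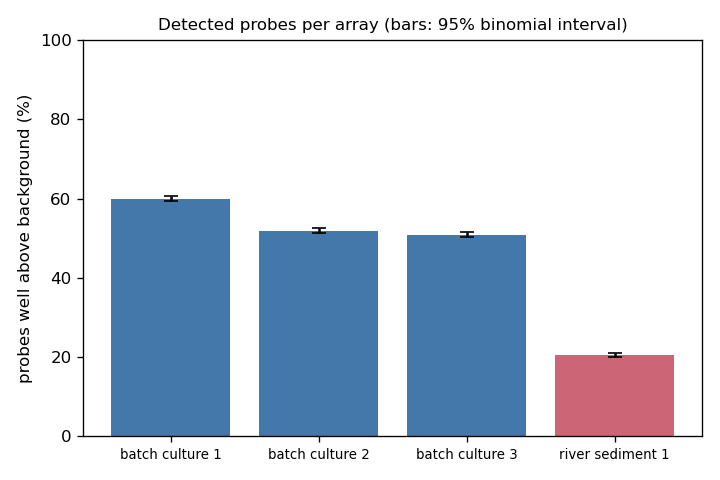
Share of the 21947 probes well above background on each array, in percent, with exact 95% binomial intervals as error bars; blue bars are batch cultures and the red bar is river sediment. River sediment stood at 20.4%, against 50.9% to 60% in the batch cultures.

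The first comparison asked which transcripts differed between cells in river sediment and cells in batch culture. In the scanner files, probe target SH4281 stood 7.24 log2 higher in river sediment (SE 0.63, limma adjusted p = 2.8e-26), at 3.19 against -4.05 ± 0.15 (SD, n = 3) relative to each array's 75th percentile. That batch mean took in a second probe with no usable spot in river sediment, and the probe measured on all 4 arrays was 7.54 higher. The latter probe was not well above background on every batch array, so the size of its rise depends on the background there. With this scaling, probe target SH0059 was at least 62.2-fold higher in river sediment. It was not well above background on any batch array (fitted log2 difference 6.8, SE 0.63, limma adjusted p = 2.9e-23). Other settings gave fitted differences below that bound: 5.7 with the 75th percentile of all probes, 5.67 with the median of detected probes and 5.6 with the scanner-processed signal. Quantile normalization gave 7.83 and the background-subtracted signal 9.91. Probe target SH0653 fell by 5.86 log2 in river sediment (SE 0.63, limma adjusted p = 3.5e-17), from 4.79 ± 0.52 (SD, n = 3) to -1.07. Probe target SH0668 was at least 21.2-fold higher in batch culture and was not well above background in river sediment (fitted log2 difference -6.04, SE 0.67, limma adjusted p = 2.8e-16). The batch culture values of SH0668 had an SD of 1.21 (n = 2), above the single spread of 0.55 log2 that its test used. The files do not pair these probe targets with gene names, and none is named here.

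The probes behind these targets differed in number and in agreement. The value of SH4281 in river sediment rested on a single probe, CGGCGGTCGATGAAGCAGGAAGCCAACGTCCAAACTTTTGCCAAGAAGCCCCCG, and its other 4 probes were left out as dim, so no difference is given for them. Of all targets tested, 916 (14.5%) likewise averaged probe sets that were not the same on every array. With only probes usable on all 4 arrays, 2960 targets were higher and 597 lower. SH0653 was measured by 3 probes, which differed by -6.32, -5.69 and -5.11. Only the probe that differed by -5.11 was well above background on all 4 arrays, and only it had usable spots on all 4. The background-subtracted river sediment spots of the probe that differed by -6.32 were 25.67 and 32.01, below the offset of 50. The larger falls may therefore be set by the background there. The fall given above for SH0653 averages all 3 probes, so its size depends on that background too. SH0059 and SH0668 were measured by 1 retained probe each, and SH0668 had usable spots on 2 of the batch arrays. Among 3134 targets with more than 1 retained probe, 18.8% had probes of both signs.

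Over all 6324 probe targets tested, 3780 (59.8%) passed an adjusted p of 0.05 in limma, 2962 higher and 818 lower in river sediment. The share of higher targets among these was 78.4%, and the median difference over all targets was 1.2 log2. That split depended on the scaling of the arrays. With the 75th percentile taken over all probes, 1963 targets were higher and 1993 lower (49.6% higher). With quantile normalization 2149 were higher and 2753 lower (43.8% higher). With the median of detected probes, 1705 were higher and 1852 lower (47.9% higher). The scanner-processed signal gave 54.9% higher and the background-subtracted signal 54.8%. Over the 3595 probes, the 75th percentile was 9.17 log2 in river sediment and 13.84, 12.66 and 12.43 in batch replicates 1, 2 and 3. Over all probes it was 8.2 against 11.53, 10.72 and 10.5, a smaller drop in river sediment. Differences therefore shifted down, by a median of -1.1 log2. A probe of equal signal on all arrays comes out higher in river sediment, more so over the 3595 probes. For the other settings the cause was not tested. Of the targets lower in river sediment, 449 were not well above background there. Nor were 942 of the 2962 that were higher. The filter kept those 942 for probes well above background on all batch arrays. Their calls as higher therefore do not show more transcript in river sediment. Batch replicates 2 and 3 shared a slide with river sediment, and within that slide 4081 targets passed, 3048 higher and 1033 lower. Slide as a block is no separate check, since batch replicate 1 was the only array on its slide and the fit amounts to leaving it out. Without batch replicate 2, 480 targets were lower. An exact permutation test of 3 arrays against 1 cannot give a p below 0.25.

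Probe targets whose names begin with U differed from those beginning with SH in the comparison of river sediment with batch culture. The files do not say what either prefix means. The array was designed on 2 genomes and 11694 probes are named SH, close to the number of shared probes in the series text, so whether U-named targets belong to 1 strain alone is open. Of 2312 U targets tested, 1625 were higher and 96 lower, with a median difference of 2.27 log2. Of 4012 SH targets tested, 1337 were higher and 722 lower, with a median of 0.47. With the 75th percentile taken over all probes, the medians were 1.18 and -0.63, and that of SH targets lay below 0 under each of the 5 other scalings and signal columns. Under each of those 5, more SH targets were called lower than higher, the reverse of the split above, and more U targets were called higher than lower. U targets had the higher median under all settings. Detection fell in both sets: 31.5% of U targets had a probe well above background in river sediment, against 56.1%, 40.3% and 41.7% in batch replicates 1, 2 and 3, and 38.1% of SH targets, against 83.3%, 77.3% and 76.6%. The median batch culture level was -3.21 for U targets and -1.83 for SH targets.

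The authors' deposited matrix of normalized log2 values names its rows by locus tag. Locus tag DSY1037 stood at 15.78 in river sediment against 6.37 ± 0.05 (SD, n = 3) in batch culture, 9.4 log2 higher (SE 0.24, limma adjusted p = 6.4e-07). DSY2839 stood at 16.06 against 7.23 ± 0.16, a difference of 8.83 (SE 0.26, limma adjusted p = 6.4e-07). DSY0472 fell by 10.22 log2 (SE 0.48, limma adjusted p = 1.3e-06), from 16.31 ± 0.71 to 6.1. DSY0474 fell by 9.2 log2 (SE 0.25, limma adjusted p = 6.4e-07), from 15.71 ± 0.12 to 6.51. In river sediment, DSY0472 and DSY0474 lay below the median of intergenic regions, 7.89. In batch culture, DSY1037 lay below the corresponding median of 7.2 and DSY2839 close to it. The sizes of these 4 differences may therefore be set by the floor of the matrix. The files do not pair locus tags with gene names or products.

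Tags numbered next to each other often moved together in the deposited matrix. The tags nearest DSY1037 followed it only in part: those numbered 1, 2, 3 and 4 below it differed by 1.22, 2.69, -1.4 and 0.16 log2 (limma adjusted p 0.054, 0.00035, 0.0063 and 0.59), and the one 2 above it by 0.05 (limma adjusted p 0.92). DSY1037 lay in a block of 224 tags, numbered 850 to 1088, of which 180 were higher and 4 lower in river sediment, with a median difference of 1.92 log2 against -1.25 for the other tags. On the 3 batch arrays the block's median level was 7.24, 6.97 and 7.09, close to the 7.2 of intergenic regions and below the 10.56 of the other tags. In river sediment the block stood at 9 and the other tags at 9.23. The limits of the block were drawn where it stood furthest from the rest, with a statistic of 21.06 against at most 4.86 in 20 shuffles. Those shuffles treated tags as independent, although differences of neighbours outside the block correlated at 0.5. They therefore cannot measure how rare such a block is. The block held 17.9% of the tags that were higher, and without it 3592 tags passed, 826 higher and 2766 lower. The 4 tags numbered just below DSY2839 were also higher in river sediment, by 5.17, 4.85, 3.58 and 7.45 log2. DSY0472 and DSY0474 lay within 16 consecutive tags that were all lower, with a median difference of -6.82. Runs of at least 5 consecutive tags, each past the threshold and at least 2 log2 apart in 1 direction, numbered 6 higher (51 tags, the longest of 21) and 78 lower (608 tags, the longest of 26). In 1000 shuffles of the tags, the most runs were 1 higher and 29 lower. The shuffles also break the order of batch culture levels, which correlated at 0.65 between neighbours and enter the difference. More runs than in the shuffles therefore do not show that neighbours changed together in river sediment.

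**Figure D2:**
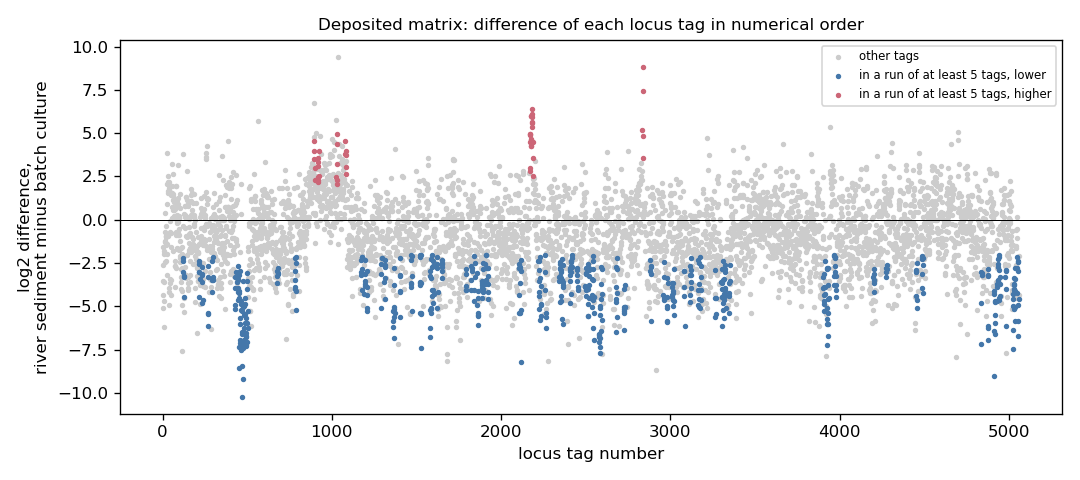
Log2 difference between river sediment and batch culture in the deposited matrix (vertical axis) for each locus tag in numerical order (horizontal axis); red and blue points lie in runs of at least 5 consecutive tags that were higher or lower. The 6 higher runs hold 51 tags and the 78 lower runs hold 608, and most points of the block from 850 to 1088 lie above 0.

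Of 4824 locus tags tested, 3775 (78.3%) passed an adjusted p of 0.05 in limma, 1005 higher and 2770 lower in river sediment. This share of 26.6% higher stood against 78.4% among the probe targets of the scanner files, with the scaling over 3595 probes. Under the other scalings and signal columns, 43.8% to 54.9% of the called probe targets were higher, still above the share in the matrix. The sets also differ. The matrix rows are locus tags, while the targets are U-named and SH-named probes of an array designed on 2 genomes. The method that normalized the matrix is not given in the sources used here. On the river sediment array, the 99th percentile lay 6.19 log2 above the median in the matrix and 2.3 above it in the background-corrected scanner signal. On batch arrays 1, 2 and 3 it lay 6.92, 6.86 and 6.9 above the median in the matrix and 7.43, 7 and 6.81 above it in the scanner signal.

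The second comparison took the intergenic regions of the deposited matrix. The region from 2389111 to 2389367 was 6.94 log2 higher in river sediment (SE 0.34, limma adjusted p = 1.7e-06), at 14.05 against 7.11 ± 0.13 (SD, n = 3). The region from 4502282 to 4502611 was 5.96 higher (SE 0.34, limma adjusted p = 3.6e-06). The region from 328324 to 328927 fell by 6.56 log2 (SE 0.55, limma adjusted p = 1.5e-05), from 15.13 ± 0.82 to 8.58. The region from 5030837 to 5030992 fell by 5.46 (SE 0.34, limma adjusted p = 4.5e-06). That last region stood at 5.51 in river sediment, below the median of intergenic regions there, 7.89, so the size of its fall may be set by the floor. Positions are as the matrix gives them for the chromosome, and the build is not named beyond the sequence record. Of 4428 intergenic regions, 2633 (59.5%) passed, 1917 higher and 716 lower, with a median difference of 0.68 log2. The median batch culture level of intergenic regions was 7.2, against 10.42 for locus tags. The same start, 101009, stood in 3292 intergenic rows with ends from 101127 to 104432, so the positions of those rows were not used. Among the other 1136 regions, tested alone, 713 were higher and 66 lower.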

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

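The removal of a probe GC trend, the restriction to probes usable on all 4 arrays, the U and SH counts by scaling, the alternative fits of the locus tags, also without a block, and the intergenic test without the repeated start were chosen after seeing the data. The total of 3780 changed probe targets stayed within 1.5 times under each setting tried except the filters. With no filter on dim probes 7711 passed (6954 higher). With only probes well above background on all 4 arrays 1700 passed (1388 higher, 312 lower), from fewer targets tested. The split by direction moved with the scaling. Higher targets numbered 1705 with the median of detected probes, 1963 with the 75th percentile of all probes and 1005 among locus tags of the matrix. Lower targets numbered 1692 with the scanner-processed signal, 1930 with the background-subtracted signal, 2753 with quantile normalization, 1852 with the median, 1993 with the 75th percentile of all probes and 2770 in the matrix. The 5 scanner settings shifted each target's difference by a median of -0.4 to -1.26 log2, with most causes untested. With the 75th percentile of all probes, 2781 of the 3780 targets were called in the same direction and 0 in the opposite one, and with quantile normalization 2821 and 204. Leaving out 1 batch replicate gave 480 (without replicate 2) to 1033 lower targets.

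Counts of locus tags stayed within 1.5 times, as did those of intergenic regions, except that without the repeated start 779 passed (713 higher, 66 lower), from 1136 tested. The named members kept direction and call in the 113 values computed, of which those with slide as a block repeat those without batch replicate 1. They were picked as the largest differences in these same data, so this says nothing about other members. The size of SH4281 with no filter, which averages in 4 dim probes, and that of SH0668 with the background-subtracted signal, where river sediment lay at the floor of 1, have no meaning. SH0668 had no value with slide as a block or without replicate 1 or 3 or with only probes usable on all arrays, nor had SH4281, SH0059 and SH0668 with only probes above background on all 4 arrays. Above the 95th percentile of negative controls stood 58.8% of probes in river sediment and 74.9%, 63.1% and 62.6% in batch cultures. Signal over background limits the river sediment levels. Gene lists (camera, fry) were not run, nor scanner-file settings for intergenic regions, which those files do not mark. No paired analysis was possible because the groups share fewer than 2 replicate numbers.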

Other observations

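The tests of tag order, of the runs of tags and of the block of adjacent tags were chosen after the result was seen. Levels of neighbouring locus tags in the deposited matrix correlated at 0.65 in batch culture and at 0.11 in river sediment, across 4627 pairs of tags, which are not independent replicates. Batch arrays correlated with each other at 0.97 over probes, and river sediment with batch arrays at 0.39 to 0.48. The first and second probe of a target correlated at 0.74, 0.75 and 0.69 in the batch cultures and at 0.32 in river sediment, over 2759 targets. Called alone against the other batch arrays, batch replicates 1, 2 and 3 differed in 137, 0 and 3 targets.

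The block of 224 tags stood out because batch culture was dim there on each of 3 arrays while river sediment was not. Drawn from batch level alone, without river sediment values, the block held 225 tags, 224 of them shared. These were 2.11 log2 higher than the 20 other tags nearest in batch level, against at most 0.66 in 4151 overlapping stretches of the same length elsewhere, which argues against a low batch level as the whole cause. A candidate explanation is that this stretch was missing from, or silent in, the batch cultures and carried in the sediment sample. No value here tells those apart, since no DNA was measured and RNA of other organisms could also bind these probes.

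Differences of neighbouring locus tags correlated at 0.54 (0.5 outside the block), above the 0.04 reached by any of 1000 shuffles, which argues against chance order. After the trend on batch culture level was removed the correlation was 0.18, between the limits set for and against a shared batch level, so that explanation stays open. RNA of other organisms binding single probes may also contribute: with trends on level and GC removed, the first and second probes of a target correlated at 0.36 (95% bootstrap 0.31 to 0.4), which does not settle it. The low correlation of neighbours' river sediment levels, 0.11 over all tags and 0.11 within the block, cannot show whether neighbours were transcribed together there. On that array even the first and second probe of a target correlated at only 0.32. The longest of the 6 higher runs, 21 tags from DSY2168 to DSY2188, had a median river sediment level of 13.62, against 9.21 over all tags.

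Targets bright in batch culture were lower in river sediment and dim ones higher, with a correlation of -0.93 across targets between the difference and the batch level, which enters the difference itself. Additive background of the kind the scanner's surface captures may narrow the river sediment values. After its subtraction their SD was still 0.36 of that in batch culture (0.34 to 0.38, 2351 targets). Those targets were taken from probes well above background in river sediment, which cuts off its dim values and itself narrows that SD. The ratio therefore cannot decide whether such background was the cause. Signal from unspecific binding that such a surface does not capture also stays open.

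Probe GC content does not account for the higher differences of U-named targets, which were 1.73 log2 above SH-named ones within bins of GC (1.62 to 1.86) and 1.81 without bins. Within bins of batch culture level the gap was 0.4 (0.34 to 0.45), so lower batch levels may account for much of it, and the remainder stays open. No biological explanation was tested, because the files do not say what the prefixes mean.

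The 4 ways of setting 1 array against the other 3 are too few for a share under 0.05. The real one gave 3780 targets and the highest of the others 0, so that 1 of 4 was as large. In those others river sediment stood among the 3 arrays and raised their spread, so the 0 adds no support.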
